A study of Mus musculus with 6 samples.

How the data were processed

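RNA from hippocampi of wild-type mice was sequenced in 6 libraries, 3 from mice given saline and 3 from mice given LPS at 1 mg per kg, collected 24 h after the injection. Per the labels, the hippocampi of 3 mice per group were taken and frozen at once, and a company did the sequencing. The authors deposited 1 table of FPKM values (fragments per kilobase, scaled to the mapped fragments of a library), a unit taken from the name of the table and from its values, which are not whole, not negative and sum to 352136 to 359694 per library. Per the submitters' processing notes, CASAVA and DESeq2 were used, without versions or roles. The aligner, quantifier, genome build, annotation and strandedness are not given in the sources used here, and no scaling between libraries is stated.

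The table holds 22589 features, of which 21587 have a gene symbol, 529 an Ensembl ID alone and 473 the name of an assembled locus. Of all IDs, 21995 (97.4%) match GENCODE M21 of GRCm38, which was used for positions and overlaps of genes and for nothing else. Depth per library is unknown. The ratios of low values between libraries show no steps of whole fragments (the commonest bin of 0.1 log2 units holds 6.3% to 8.39% of genes under 0.1 FPKM), so no interval or limit for counting error was computed. Genes encoded by the mitochondrial genome take 16.6% to 19.6% of the summed FPKM. Gapdh averages 14.7 FPKM and Pgk1 178 FPKM, and levels of genes with many pseudogenes are uncertain.

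Values were taken as log2(FPKM + 0.5) over genes with a mean of at least 0.5 FPKM in the 6 libraries, 13992 genes, and LPS was compared with saline in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05, no fold minimum). Errors given beside FPKM values are SD over 3 libraries, and those beside log2 differences are SE of the fit. Where a library is listed at 0, each value is given in place of a mean. The log2 scale with the added 0.5 understates folds of low genes, and their size depends on the value added. The exact two-sided permutation test of the log2 values was run for Numb and Ifi204. Of 49 gene lists written before the data were examined, 46 with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The list of X inactivation and Y-linked genes was not tested, and the lists of the title genes and of lymphocyte markers had under 3 tested members, with Jchain as the 1 lymphocyte gene (not past the threshold). Camera was repeated with an estimated correlation, and fry asked whether the genes of a list moved 1 way on balance. Lists were adjusted over the list alone as well as over all genes.

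The genes named in the text follow a rule fixed before the data were examined. Numb and Ifi204 are always named. The 12 genes with the largest rise and the 12 with the largest fall were taken among those with a symbol, a mean of at least 1 FPKM, an adjusted p under 0.05 and no overlap between groups, and the 4 genes with the smallest p were taken from each list. Some genes that the rule takes are not reported here. Other genes are marked as named after their values were seen. The design, the lists and the alternatives were also fixed before the data were examined, except for those marked as added later.

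Alternatives changed 1 choice at a time. They were pseudocounts of 0.1 and 1, no filter and means of at least 1 and 5 FPKM, scaling to equal sums, median-of-ratios size factors, quantile normalization, no variance trend, robust variance, array weights, a fold minimum of 1.2 (treat), each library left out, the estimated correlation, fry and each gene in 1 list. Sex as a covariate, Ttr as a covariate and leaving out both libraries high in choroid plexus genes were added after seeing the data. Sex was taken from the summed FPKM of 4 Y-linked genes, with a limit of 1 FPKM. With LPS and sex in 1 limma fit, an interaction on 2 residual degrees of freedom, 0 genes passed for the interaction (562 at an unadjusted p under 0.05), and 4 genes passed for sex beside LPS.

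On simulated data with 13991 genes and 50 changed genes per fold, the test recovered 52% of genes changed 1.5-fold, 86% at 2-fold, 100% at 4-fold and 94% at 8-fold. Of 182 calls 16 were false (8.79%, above the nominal 5%). Camera found 40 of 40 shifted lists and called 2 of 40 unshifted ones. The simulated genes varied independently of each other. These counts therefore do not give camera's error rate for lists whose genes vary together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Raw reads were not used here.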

Results

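The transcriptome of the mouse hippocampus was measured by RNA sequencing 24 h after an intraperitoneal injection of sterile saline or of lipopolysaccharide (LPS), the cell wall component of Gram-negative bacteria that activates innate immunity through Toll-like receptor 4. The LPS came from Salmonella and was given at 1 mg per kg body weight to wild-type mice 6 to 8 weeks old. The labels state 3 mice per group, so saline replicates 1 to 3 and LPS replicates 4 to 6 were taken as separate animals, and p-values measure the spread between them. If a library pools mice, which the labels do not exclude, p-values measure the spread between pools. The series title names Numb, an adaptor protein known as an inhibitor of Notch signalling, and Ifi204, an interferon-inducible DNA sensor of the PYHIN family, and sets both beside microglial activation. The comparison therefore asks which hippocampal transcripts differed after LPS, and where these 2 genes stood. All 6 libraries came as FPKM values summing to between 352136 and 359694 per library, with 16921 to 17230 genes above 0. Read depth is unknown, and no interval for counting error can be given. Pearson correlations of log2 values over genes ranged from 0.985 to 0.991 within saline, from 0.973 to 0.988 within LPS and from 0.947 to 0.974 between the groups. The labels give no sex, and the summed FPKM of 4 Y-linked genes was 35.2 to 55.9 in saline replicates 1 and 3 and LPS replicate 4 and at most 0.0859 in the others, so saline held 2 males and 1 female and LPS 1 male and 2 females.

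After LPS the hippocampus held acute-phase, chemokine and immune receptor transcripts that were near 0 in saline, while 8 of 19 tested genes of resting microglia fell. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, stood at 0, 0.187, 0 FPKM in saline replicates 1 to 3 and 212, 139, 311 FPKM in LPS replicates 4 to 6 (adjusted p = 3.16e-05, limma). Saa3, an acute-phase serum amyloid gene, was listed at 0 in the saline libraries and at 135, 45.1, 101 FPKM in LPS (adjusted p = 0.000118). Of the genes with the largest rises, Ms4a6c went from 0.264 ± 0.115 to 10.4 ± 2.76 FPKM (mean ± SD, n = 3 per group) and Ms4a6d from 0.584 ± 0.134 to 9.13 ± 1.72 FPKM. Plin4, a lipid droplet coat protein gene, rose from 0.451 ± 0.118 to 11.2 ± 2.69 FPKM, 12.1-fold higher on the log2(FPKM + 0.5) scale, which understates the change of low genes. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 9.46-fold, from 3.96 ± 0.537 to 45.8 ± 25.6 FPKM. The protease inhibitor gene Ctla2a rose 20.2-fold and stood at 2.19, 2.43, 2.26 FPKM in saline replicates 1 to 3 and 27.8, 38.9, 161 FPKM in LPS replicates 4 to 6. Its neighbour Ctla2b rose 8.42-fold. The calprotectin subunit gene S100a9 stood at 0.0627, 0, 0.12 FPKM in saline replicates 1 to 3 and 4.68, 5.7, 2.54 FPKM in LPS replicates 4 to 6. Chemokine gene Ccl5 rose from 0.232 ± 0.115 to 9.9 ± 7.65 FPKM, and Ccl21e, 1 of several near-identical copies, from 1.37 ± 1.69 to 11.4 ± 0.298 FPKM. Npcd stood at 1.11, 0, 0 FPKM in saline replicates 1 to 3 and 8.04, 7.8, 17.5 FPKM in LPS replicates 4 to 6 and shares its locus with Nptxr and Cbx6 on the same strand, so its reads are uncertain. Ccl5 lost its call without saline replicate 1 (adjusted p = 0.0622). Ccl5 and Ccl21e lost their calls without saline replicate 3 (adjusted p = 0.0594 to 0.0718), with a range of 0.00116 to 0.0718 over the alternatives for these genes.

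Among genes that the naming rule takes, the largest falls on the log2(FPKM + 0.5) scale were those of 2 microglial receptor genes. These were Gpr34, 5.03-fold lower at 6.97 ± 0.478 to 1.01 ± 0.33 FPKM (adjusted p = 0.000612, limma), and P2ry12, 4.83-fold lower at 18.5 ± 1.11 to 3.45 ± 0.25 FPKM (adjusted p = 5.4e-05). Ugt8a, whose product makes the myelin lipid galactosylceramide, fell 3.67-fold from 15.3 ± 3.96 to 3.86 ± 1.39 FPKM, and the oligodendrocyte gene Opalin fell 3.1-fold. Pltp, which encodes phospholipid transfer protein, fell from 29.1 ± 4.03 to 8.43 ± 2.68 FPKM, and the fatty acid binding protein gene Fabp7 from 32.7 ± 4.3 to 10.2 ± 3.12 FPKM. Slc22a8, an organic anion transporter gene of the blood-brain barrier, fell 3.29-fold, Itm2a 3.28-fold, Serpinb1a 3.56-fold and Apln, the gene of the vascular peptide apelin, 3.18-fold. Gm26920, which overlaps Zfp82 and Zfp566 on the same strand, stood at 1.85, 2.25, 1.69 FPKM in saline replicates 1 to 3 and 0, 0, 0.565 FPKM in LPS replicates 4 to 6. Over the 13992 genes tested, 1221 were higher and 827 lower after LPS at an adjusted p under 0.05, 286 and 61 of them by at least 2-fold. The 3 values of each group did not overlap in 5574 genes (39.8%, against 10% by chance). The counts fell to 312 higher and 92 lower without saline replicate 1 and to 500 and 235 without saline replicate 2. They fell to 403 and 204 without saline replicate 3 and to 752 and 464 without LPS replicate 5. With sex as a covariate, an alternative chosen after the data were seen, 574 genes were higher and 274 lower. The strandedness of the libraries is not given in the sources used here, and Gpr34, P2ry12, Plin4 and Pltp overlap Cask, Med12l, Hdgfl2 and Ctsa on the opposite strand. Ctla2a and Ctla2b overlap predicted genes on their own strand. Reads of these pairs are uncertain. Opalin and Gm26920 lost their calls without saline replicate 1 (adjusted p = 0.0533 to 0.0539), with a range of 0.000925 to 0.0539 over the alternatives for these genes.

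Of the genes in the series title, Ifi204 rose and Numb did not pass the threshold. Ifi204 stood at 0.137, 0.185, 0.0636 FPKM in saline replicates 1 to 3 and 1.86, 2, 1.89 FPKM in LPS replicates 4 to 6, a log2 difference of 1.95 ± 0.15 (SE, adjusted p = 0.000613, limma) or 3.86-fold on the log2(FPKM + 0.5) scale. That size depends on the added 0.5, since the log2 difference was 3.18 with 0.1 added and 1.37 with 1 added. Numb stood at 9.48, 11.2, 9.32 FPKM in saline replicates 1 to 3 and 9.03, 7.96, 7.57 FPKM in LPS replicates 4 to 6, a log2 difference of -0.27 ± 0.10 (adjusted p = 0.114). For both genes the 3 saline and 3 LPS values did not overlap, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. In the GENCODE M21 annotation of GRCm38, Numb (ENSMUSG00000021224) lies on chromosome 12 from 83794034 to 83921934 on the minus strand. Ifi204 (ENSMUSG00000073489) lies on chromosome 1 from 173747293 to 173766943, also on the minus strand. Numb shares its locus with Gm3791 on the same strand and with Gm46367 and Gm47748 on the other, and Ifi204 has close PYHIN paralogs, so reads of both could have been split or shared.

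**Figure D1:**
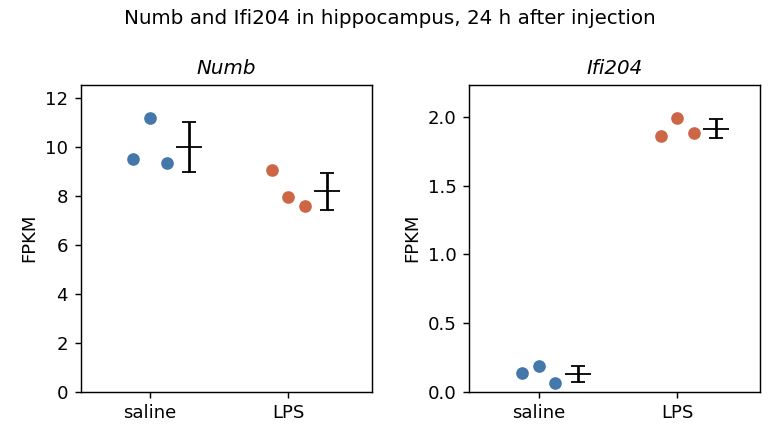
FPKM of Numb and Ifi204 (vertical axes, FPKM) in the saline and LPS groups, with 1 point per library and the mean ± SD of 3 libraries in black beside the points. Ifi204 lies between 0.0636 and 0.185 FPKM in saline and between 1.86 and 2.00 FPKM in LPS, while Numb lies between 9.32 and 11.2 FPKM in saline and between 7.57 and 9.03 FPKM in LPS.

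Around the title genes, the PYHIN, Notch and cGAS-STING lists were past the threshold, as up, with directional fry (adjusted p = 0.0045, 0.0486 and 0.013) and not with camera. Of 4 tested PYHIN genes, Ifi204 was higher, Mndal lower (4.44 ± 0.565 to 2.56 ± 0.703 FPKM, adjusted p = 0.0374, limma), and Ifi203 and Aim2 were not past the threshold, at 2.34 ± 0.27 to 1.51 ± 0.429 FPKM and 2.19 ± 0.812 to 3.04 ± 0.225 FPKM (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.864, adjusted p = 0.935 with an estimated correlation). With no filter 4 of 12 PYHIN genes rose and 0 fell, and the list was past the threshold with camera (adjusted p = 0.015, range over the camera alternatives 0.015 to 0.991). Mndal, Ifi203 and Ifi211 overlap on 1 strand. Of 20 genes of Numb and Notch signalling, Notch4 and Heyl rose and Numbl, the paralog of Numb, fell from 40.7 ± 0.444 to 34.8 ± 1.72 FPKM (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.406, adjusted p = 0.554 with an estimated correlation). The cGAS-STING list had 3 higher and 1 lower of 11 (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.257, adjusted p = 0.446 with an estimated correlation). There Irf7, a transcription factor of the interferon response, rose from 0.759 ± 0.1 to 5.07 ± 1.89 FPKM, the DNA sensor gene Cgas from 0.746 ± 0.0713 to 1.52 ± 0.224 FPKM and the kinase gene Tbk1 from 15.4 ± 0.346 to 20.1 ± 1.38 FPKM, and the helicase gene Ddx41 fell from 16.1 ± 0.667 to 13.2 ± 0.347 FPKM. Mndal, Notch4, Heyl, Numbl, Cgas, Tbk1 and Ddx41 lost their calls without saline replicate 1 (adjusted p = 0.0652 to 0.139). Mndal, Numbl, Cgas, Tbk1 and Ddx41 lost their calls without saline replicate 2 (adjusted p = 0.0582 to 0.0959). Mndal, Heyl, Numbl, Cgas, Tbk1 and Ddx41 lost their calls without saline replicate 3 (adjusted p = 0.0631 to 0.118). Mndal, Heyl, Numbl and Ddx41 lost their calls without LPS replicate 4 (adjusted p = 0.0511 to 0.0902). Heyl, Cgas and Ddx41 lost their calls without LPS replicate 5 (adjusted p = 0.0653 to 0.0842). Mndal, Heyl and Numbl lost their calls without LPS replicate 6 (adjusted p = 0.0577 to 0.0688). Mndal, Heyl, Numbl, Cgas and Ddx41 lost their calls with sex as a covariate (adjusted p = 0.0631 to 0.0928), with a range of 0.00541 to 1 over the alternatives for these genes.

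Interferon-response genes rose together. Of 30 tested genes of the type I interferon response, 24 rose and 0 fell (28 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.38e-15, adjusted p = 0.117 with an estimated correlation). Among them, the antiviral membrane protein gene Ifitm3 rose from 8.64 ± 1.57 to 60 ± 13.7 FPKM (adjusted p = 0.000438, limma), Ifit3 from 2.76 ± 0.22 to 9.35 ± 2.12 FPKM, Oasl2 from 0.909 ± 0.0905 to 3.68 ± 0.224 FPKM and the nucleic acid sensor gene Zbp1 from 0.0426 ± 0.00856 to 1.73 ± 0.621 FPKM. The interferon-inducible GTPases had 11 higher of 15 and 0 lower (15 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.28e-09, adjusted p = 0.226 with an estimated correlation), with Gbp2 going from 1.22 ± 0.213 to 7.57 ± 2.73 FPKM and Iigp1 from 0.718 ± 0.0394 to 3.94 ± 1.52 FPKM. Class I antigen presentation had 14 higher of 19 and 0 lower (18 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.39e-10, adjusted p = 0.142 with an estimated correlation). H2-K1, a classical class I heavy chain gene, rose from 11.5 ± 1.71 to 38.3 ± 7.35 FPKM, H2-T23 from 2.52 ± 0.284 to 10.5 ± 2.54 FPKM and the immunoproteasome subunit gene Psmb8 from 1.6 ± 0.308 to 4.72 ± 0.638 FPKM. Genes of these families resemble each other closely, and reads may be divided among them.

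Inflammatory signalling lists also rose. Of 33 cytokines and chemokines 19 were tested, 7 rose and 2 fell (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.142 with an estimated correlation). The filter keeps members near 0 FPKM in saline only where they rise, and with no filter the list stayed past the threshold. Il1b, Tnf and Il6, named after their values were seen, lay under the filter and were not tested. Il1b stood at 0.655, 0.479, 0.0961 FPKM in LPS replicates 4 to 6, Tnf at 0.563, 0.479, 0.117 FPKM and Il6 at 0.0535, 0, 0.108 FPKM. Cxcl1, a neutrophil-attracting chemokine gene, rose from 0.0927 ± 0.0364 to 4.25 ± 0.828 FPKM, the interferon-induced Cxcl10 from 0.263 ± 0.275 to 3.26 ± 0.575 FPKM and the growth factor gene Csf1 from 6.43 ± 0.484 to 12.3 ± 0.763 FPKM, while Ccl2 stood at 0, 0.136, 0.0925 FPKM in saline replicates 1 to 3 and 0.817, 1.25, 1.32 FPKM in LPS replicates 4 to 6. The 2 that fell, Il33 (14.8 ± 0.943 to 9.12 ± 1.77 FPKM) and Cx3cl1 (144 ± 3.47 to 124 ± 6.11 FPKM), are named after their values were seen. This list was not past the threshold without LPS replicate 5 (adjusted p = 0.0532, range over the camera alternatives 0.000198 to 0.825), and among members with a mean of at least 5 FPKM its direction turned (adjusted p = 0.825). Toll-like receptor and NF-kB signalling had 11 higher of 25 and 0 lower (16 higher and 0 lower adjusted over the list alone, camera adjusted p = 8.56e-08, adjusted p = 0.118 with an estimated correlation), among them the LPS co-receptor gene Cd14, from 1.06 ± 0.253 to 3.62 ± 0.171 FPKM, and Tlr2, from 0.491 ± 0.0647 to 2.72 ± 0.723 FPKM. JAK-STAT and SOCS genes had 9 higher of 17 and 0 lower (10 higher and 0 lower adjusted over the list alone, camera adjusted p = 4.13e-05, adjusted p = 0.142 with an estimated correlation), with Il4ra rising from 0.679 ± 0.13 to 3.64 ± 0.942 FPKM. Of 14 inflammasome and pyroptosis genes 9 were tested under the same filter, 5 rose and 0 fell (6 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.131 with an estimated correlation). Casp4, which encodes the mouse caspase-11 that senses intracellular LPS, rose from 0.147 ± 0.11 to 0.924 ± 0.0618 FPKM. The inflammasome list was not past the threshold among members with a mean of at least 5 FPKM (adjusted p = 0.172, range over the camera alternatives 0.000277 to 0.172). The other 4 that rose were Nek7, Txnip, Casp8 and Gsdmd, the last named after its values were seen. Il33, Cx3cl1, Casp4, Nek7, Txnip, Casp8 and Gsdmd lost their calls without saline replicate 1 (adjusted p = 0.0526 to 0.139). Il33, Cx3cl1, Nek7, Casp8 and Gsdmd lost their calls without saline replicate 2 (adjusted p = 0.0542 to 0.102). Il33, Cx3cl1, Nek7, Txnip, Casp8 and Gsdmd lost their calls without saline replicate 3 (adjusted p = 0.0663 to 0.119). Casp8 and Gsdmd lost their calls without LPS replicate 4 (adjusted p = 0.0608 to 0.0768). Cx3cl1, Nek7 and Casp8 lost their calls without LPS replicate 5 (adjusted p = 0.0529 to 0.0793). Cx3cl1, Casp8 and Gsdmd lost their calls without LPS replicate 6 (adjusted p = 0.0612 to 0.0654). Il33, Cx3cl1, Casp8 and Gsdmd lost their calls with sex as a covariate (adjusted p = 0.0505 to 0.0919), with a range of 0.000495 to 1 over the alternatives for these genes.

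**Figure D2:**
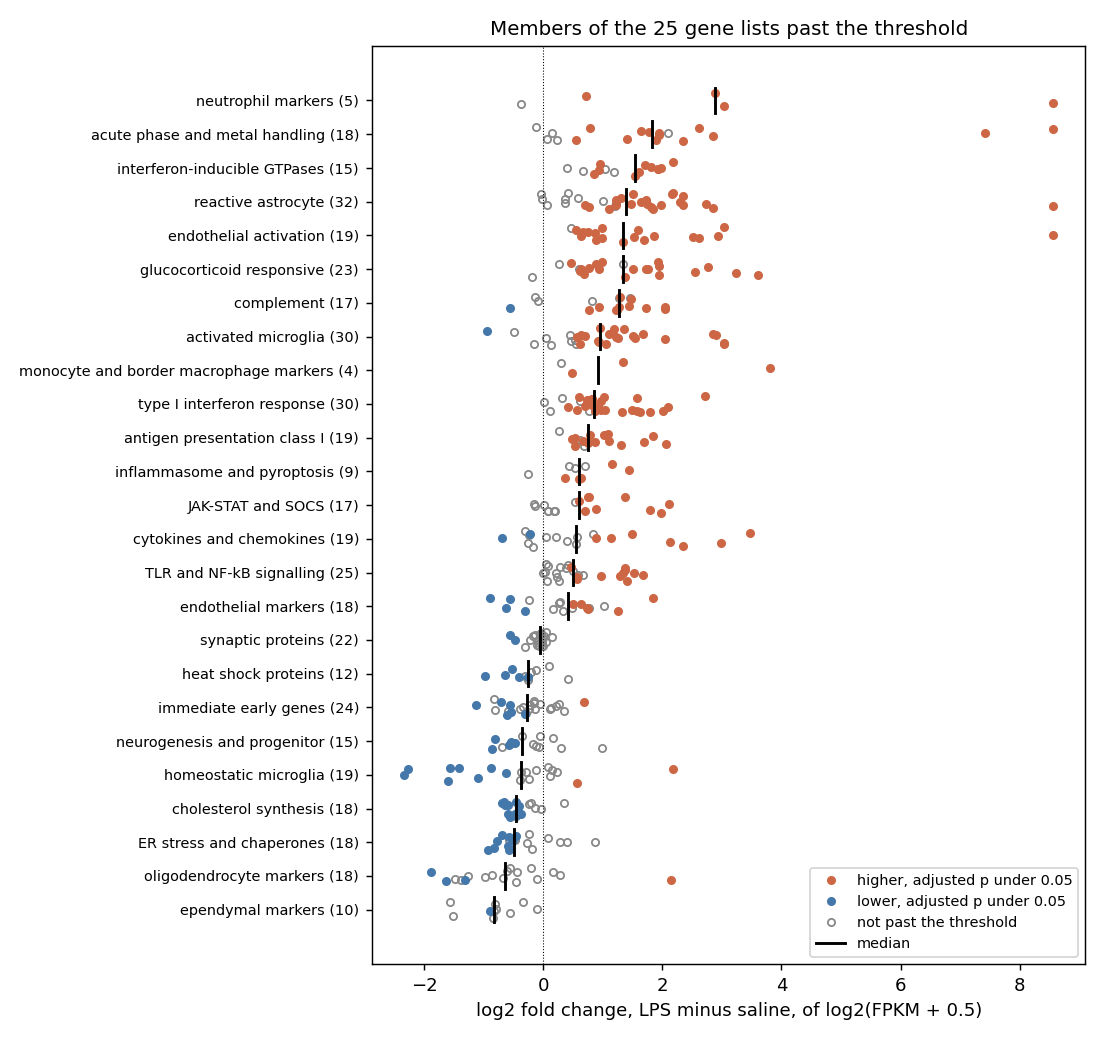
Log2 fold changes (horizontal axis, LPS minus saline, of log2(FPKM + 0.5)) of the tested members of the 25 gene lists past the threshold, with the number of tested members in parentheses. Filled points are members past the threshold (orange higher, blue lower), open points are not, and the black bar is the median of the list, which runs from -0.82 for ependymal markers to 2.88 for neutrophil markers.

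Microglial genes moved apart. Of 19 tested genes of resting (homeostatic) microglia, 8 fell and 2 rose (2 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00118, adjusted p = 0.347 with an estimated correlation). Besides P2ry12 and Gpr34, Siglech fell from 7.52 ± 0.546 to 2.15 ± 0.315 FPKM, a log2 difference of -1.60 ± 0.12 (adjusted p = 0.000593, limma). The 2 that rose were Gpr84, a receptor gene known from activated myeloid cells, from 0.368 ± 0.0425 to 3.6 ± 1.43 FPKM, and the phagocytic receptor gene Mertk, named after its values were seen, from 8.83 ± 0.487 to 13.3 ± 0.395 FPKM. Of 30 tested genes of activated microglia, 21 rose and 1 fell (22 higher and 3 lower adjusted over the list alone, camera adjusted p = 8.18e-12, adjusted p = 0.117 with an estimated correlation). Fc receptor genes Fcgr3 and Fcgr4 rose from 6.82 ± 0.0666 to 21 ± 2.29 FPKM and from 0.0644 ± 0.0221 to 3.73 ± 0.614 FPKM, the cholesterol 25-hydroxylase gene Ch25h from 0.178 ± 0.0502 to 5.1 ± 1.09 FPKM and the scavenger receptor gene Msr1 from 0.0378 ± 0.0171 to 3.99 ± 0.967 FPKM. The 1 that fell was the lipid receptor gene Trem2, from 8.11 ± 1.32 to 3.98 ± 0.325 FPKM (adjusted p = 0.00635), named after its values were seen. Complement had 11 higher and 1 lower of 17 (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.4e-07, adjusted p = 0.117 with an estimated correlation), with C1qa rising from 32.5 ± 2.33 to 77.9 ± 7.6 FPKM, C1qb from 31.1 ± 1.37 to 73.7 ± 7.59 FPKM and the C5a receptor gene C5ar1 from 0.155 ± 0.0664 to 2.21 ± 0.182 FPKM. The 1 lower complement gene was Cfp, from 10.8 ± 0.497 to 7.22 ± 0.695 FPKM, also named after its values were seen. Per library, the median of the homeostatic list stood -0.17, -0.25 and -0.91 from the saline mean (log2) in LPS replicates 4, 5 and 6. Among members with a mean of at least 5 FPKM that list was not past the threshold (adjusted p = 0.368, range over the camera alternatives 0.000402 to 0.368). Cfp lost its call without saline replicate 1 (adjusted p = 0.0622), with a range of 0.00381 to 0.157 over the alternatives.

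**Figure D3:**
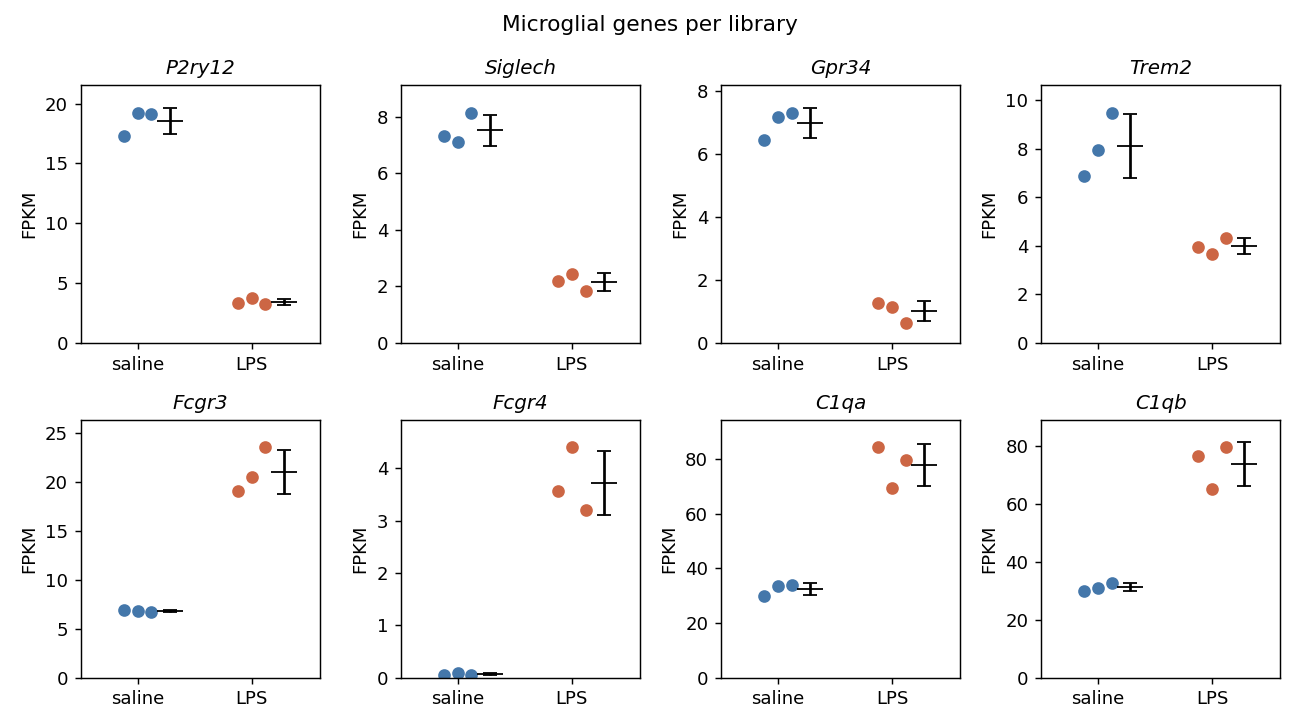
FPKM (vertical axes) of 8 microglial and complement genes in the saline and LPS groups, with 1 point per library and the mean ± SD of 3 libraries in black beside the points. P2ry12, Siglech, Gpr34 and Trem2 are lower in each LPS library than in each saline library, and Fcgr3, Fcgr4, C1qa and C1qb are higher.

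Markers of neutrophils, monocytes and border macrophages were few above the filter. Of 17 neutrophil markers 5 were tested and 4 rose (4 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00068, adjusted p = 0.142 with an estimated correlation), namely Lcn2, S100a8, S100a9 and the protease gene Mmp9. S100a8 was listed at 0 in saline and at 4.64, 3.44, 1.95 FPKM in LPS, and Lcn2 is also a known product of reactive astrocytes and endothelium. Of 16 monocyte and border macrophage markers 4 were tested and 3 rose (3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000696, adjusted p = 0.117 with an estimated correlation), namely Ms4a6c, Ly6c2, from 0.335 ± 0.101 to 1.63 ± 0.294 FPKM, and Vcan, which is also a marker of oligodendrocyte precursors. The filter keeps markers near 0 FPKM in saline only where they rise, and with no filter 12 of 30 markers of both lists rose and 0 fell. Mmp9 passed narrowly (adjusted p = 0.04997) and lost its call under 13 of 19 alternatives, pseudocounts of 0.1 and 1 and no filter among them. Mmp9 and Vcan lost their calls without saline replicate 1 (adjusted p = 0.106 to 0.121). Mmp9 and Vcan lost their calls without saline replicate 2 (adjusted p = 0.0819 to 0.136). Mmp9 lost its call without saline replicate 3 (adjusted p = 0.101). Mmp9 lost its call without LPS replicate 4 (adjusted p = 0.103). Mmp9 and Vcan lost their calls without LPS replicate 5 (adjusted p = 0.0633 to 0.123). Mmp9 and Vcan lost their calls with sex as a covariate (adjusted p = 0.0557 to 0.0686), with a range of 0.012 to 0.377 over the alternatives for these genes.

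Acute-phase, reactive astrocyte and endothelial activation genes rose. Of 28 genes of acute phase and metal handling 18 were tested, 13 rose and 0 fell (15 higher and 0 lower adjusted over the list alone, camera adjusted p = 8.42e-12, adjusted p = 0.117 with an estimated correlation). Here too the filter keeps members near 0 FPKM in saline only where they rise. Serpina3n, a serine protease inhibitor gene, rose from 21.1 ± 2.57 to 156 ± 18.6 FPKM (adjusted p = 6.88e-05, limma) and Cp, the gene of the copper carrier ceruloplasmin, from 2.65 ± 0.207 to 16.1 ± 4.89 FPKM. Of 32 tested reactive astrocyte genes 22 rose and 0 fell (24 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.38e-15, adjusted p = 0.142 with an estimated correlation), with Aspg rising from 1.03 ± 0.205 to 7.05 ± 0.82 FPKM and the proteoglycan gene Srgn from 5.03 ± 0.623 to 24.5 ± 5.69 FPKM. Of 20 general astrocyte markers 3 rose and 4 fell, and the list was not past the threshold (4 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.684, adjusted p = 0.935 with an estimated correlation). The 3 were Gjb6, Cbs and Fgfr3, and the 4 were Kcnj10, Aqp4, Acsbg1 and Gja1, the last 3 named after their values were seen. Endothelial activation had 18 higher of 19 and 0 lower (18 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.38e-15, adjusted p = 0.0694 with an estimated correlation). The leukocyte adhesion gene Icam1 rose from 0.742 ± 0.129 to 8.99 ± 0.81 FPKM (adjusted p = 7.78e-05) and Tgm2, which encodes a transglutaminase, from 2.25 ± 0.234 to 9.55 ± 1.66 FPKM. General endothelial markers went both ways, 6 higher and 4 lower of 18 (11 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.574 with an estimated correlation). Ly6c1 rose from 23.6 ± 0.955 to 86.5 ± 8.9 FPKM and the adhesion gene Pecam1 from 4.64 ± 0.111 to 11.8 ± 1.78 FPKM, while the VEGF receptor gene Kdr fell from 3.1 ± 0.105 to 1.85 ± 0.2 FPKM. The other 3 lower ones were Sox17, Ptprb and Flt1, the last 2 named after their values were seen. The endothelial list was not past the threshold with each gene counted in 1 list (adjusted p = 0.0511, range over the camera alternatives 0.000262 to 0.574) or without the variance trend (adjusted p = 0.0551). Of 15 blood-brain barrier genes 4 rose and 1 fell (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.27, adjusted p = 0.769 with an estimated correlation), with the lipid transporter gene Mfsd2a rising from 7.46 ± 0.895 to 15.9 ± 1.03 FPKM and the thyroxine transporter gene Slco1c1 falling from 22.7 ± 3.54 to 9.41 ± 1.2 FPKM, and Lsr, Slc2a1 and Slco1a4, the last named after its values were seen, also higher. Lcn2, Serpina3n and Cp are members of more than 1 of these lists. Fgfr3, Kcnj10, Aqp4, Acsbg1, Gja1, Kdr, Sox17, Ptprb, Flt1, Lsr, Slc2a1 and Slco1a4 lost their calls without saline replicate 1 (adjusted p = 0.0526 to 0.139). Aqp4, Acsbg1, Gja1, Kdr, Ptprb, Flt1, Slc2a1 and Slco1a4 lost their calls without saline replicate 2 (adjusted p = 0.0574 to 0.13). Aqp4, Acsbg1, Gja1, Kdr, Sox17, Ptprb, Flt1, Slc2a1 and Slco1a4 lost their calls without saline replicate 3 (adjusted p = 0.0609 to 0.142). Aqp4, Ptprb, Flt1 and Slco1a4 lost their calls without LPS replicate 4 (adjusted p = 0.0562 to 0.0814). Acsbg1, Gja1, Ptprb and Flt1 lost their calls without LPS replicate 5 (adjusted p = 0.0798 to 0.1). Acsbg1, Flt1 and Slco1a4 lost their calls without LPS replicate 6 (adjusted p = 0.0581 to 0.0763). Aqp4, Acsbg1, Gja1, Ptprb, Flt1 and Slco1a4 lost their calls with sex as a covariate (adjusted p = 0.0605 to 0.104), with a range of 0.00213 to 1 over the alternatives for these genes.

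Glucocorticoid-responsive genes rose as well, 19 of 23 tested and 0 lower over all genes (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.61e-15, adjusted p = 0.1 with an estimated correlation). Besides Plin4, Hif3a rose from 0.493 ± 0.0537 to 5.32 ± 0.563 FPKM (adjusted p = 0.000132, limma), the kinase gene Sgk1 from 19 ± 2.08 to 66.3 ± 12.2 FPKM and the mTORC1 inhibitor gene Ddit4 from 22.5 ± 0.276 to 43.5 ± 3.49 FPKM. Several members, such as Cdkn1a, also respond to other stimuli.

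Genes of protein folding and sterol synthesis fell by less than 2-fold. Of 18 tested genes of endoplasmic reticulum stress and chaperones 9 fell and 0 rose (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 2.87e-06, adjusted p = 0.142 with an estimated correlation). The chaperone genes Hspa5, Calr and Hsp90b1 fell from 129.8 ± 11.4 to 72.7 ± 5.53 FPKM, from 172 ± 11.3 to 100.3 ± 8.08 FPKM and from 133 ± 7.95 to 88.2 ± 2.58 FPKM, and the disulfide isomerase gene Pdia6 from 60.7 ± 5.12 to 31.8 ± 1.01 FPKM (adjusted p = 0.000641, limma). Heat shock proteins had 5 lower of 12 and 0 higher (0 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.000169, adjusted p = 0.231 with an estimated correlation), with Hspa8 falling from 653 ± 24.4 to 422 ± 37.6 FPKM and Hsph1 from 97.5 ± 5.62 to 50.1 ± 9.71 FPKM, beside Hspe1, Chordc1 and, named after its values were seen, Dnaja1. Cholesterol synthesis had 13 lower of 18 and 0 higher (0 higher and 13 lower adjusted over the list alone, camera adjusted p = 1.65e-09, adjusted p = 0.117 with an estimated correlation). Msmo1 fell from 33.3 ± 1.79 to 21 ± 0.387 FPKM and the synthase gene Hmgcs1 from 61.7 ± 4.06 to 39.5 ± 3.37 FPKM. Chordc1 and Dnaja1 lost their calls without saline replicate 1 (adjusted p = 0.127 to 0.128). Chordc1 and Dnaja1 lost their calls without saline replicate 2 (adjusted p = 0.0846 to 0.0893). Chordc1 and Dnaja1 lost their calls without saline replicate 3 (adjusted p = 0.0736 to 0.0884). Dnaja1 lost its call without LPS replicate 4 (adjusted p = 0.0778). Chordc1 and Dnaja1 lost their calls without LPS replicate 5 (adjusted p = 0.0527 to 0.0622). Chordc1 and Dnaja1 lost their calls with sex as a covariate (adjusted p = 0.0781), with a range of 0.006 to 1 over the alternatives for these genes.

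Of 5 neuronal lists, those of immediate early, synaptic and neurogenesis genes were past the threshold as lower. Immediate early genes, which neurons induce on activity, had 6 lower and 1 higher of 24 (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.347 with an estimated correlation), with Egr1 falling from 26.8 ± 1.52 to 16.3 ± 1.91 FPKM (adjusted p = 0.00573, limma). The 1 that rose, Per1 (15.3 ± 1.53 to 25.4 ± 6.82 FPKM), is also a clock gene and glucocorticoid-responsive, and is named after its values were seen. Of 22 synaptic protein genes 2 fell, the scaffold genes Homer1, from 35.1 ± 2.79 to 23.7 ± 2.58 FPKM, and Shank1, from 37 ± 2.31 to 26.5 ± 2.77 FPKM, and 0 rose (0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0346, adjusted p = 0.156 with an estimated correlation). The synaptic list was not past the threshold under 10 alternatives, among them without saline replicate 2, saline replicate 3 or LPS replicate 4 (adjusted p = 0.0606, 0.064 and 0.0716, range over the camera alternatives 0.0116 to 0.234). Neurogenesis and progenitor genes had 5 lower of 15 and 0 higher (0 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00183, adjusted p = 0.117 with an estimated correlation), with Hopx, a marker of quiescent neural stem cells and of astrocytes, falling from 40.8 ± 2.54 to 22.3 ± 3.32 FPKM. Calb2, Tubb3 and Stmn1 were also lower. Excitatory neuron markers had 2 higher and 1 lower of 20 (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.783, adjusted p = 0.935 with an estimated correlation), and inhibitory neuron markers 0 higher and 3 lower of 17 (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.065, adjusted p = 0.601 with an estimated correlation). Neither list was past the threshold. The inhibitory list was past it, as lower, without saline replicate 3 and without LPS replicate 6 (adjusted p = 0.0222 and 0.00868, range over the camera alternatives 0.00868 to 0.601). The peptide gene Cck fell from 208 ± 18.8 to 147 ± 2.26 FPKM, C1ql3 and Grin1 rose, and the 3 lower inhibitory markers were Calb2, Dlx1 and Npy. Per1, Homer1, Shank1, Calb2, Tubb3, Stmn1, C1ql3, Grin1, Dlx1 and Npy lost their calls without saline replicate 1 (adjusted p = 0.0526 to 0.127). Per1, Homer1, Shank1, Tubb3, Stmn1, Grin1, Dlx1 and Npy lost their calls without saline replicate 2 (adjusted p = 0.0523 to 0.107). Per1, Shank1, C1ql3, Dlx1 and Npy lost their calls without saline replicate 3 (adjusted p = 0.054 to 0.12). Npy lost its call without LPS replicate 4 (adjusted p = 0.0759). Per1, Tubb3, Grin1, Dlx1 and Npy lost their calls without LPS replicate 5 (adjusted p = 0.0531 to 0.0896). Per1, Stmn1, Dlx1 and Npy lost their calls with sex as a covariate (adjusted p = 0.0628 to 0.077), with a range of 0.00274 to 1 over the alternatives for these genes.

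Oligodendrocyte and ventricular markers differed between mice of 1 group. Of 18 oligodendrocyte markers 3 fell and 1 rose (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00224, adjusted p = 0.614 with an estimated correlation). Those that fell were Ugt8a, Opalin and Gjb1, and the 1 that rose was Apod, a lipid-binding apolipoprotein gene, from 67.9 ± 7.91 to 304 ± 49.8 FPKM (adjusted p = 0.000268, limma). Per library, the median of the oligodendrocyte markers stood 0.37, -0.26 and -0.13 from the saline mean (log2) in saline replicates 1 to 3, and -0.70, -0.17 and -1.09 in LPS replicates 4 to 6. Ependymal markers had 1 lower of 10, Tmem107 (6.69 ± 1.17 to 3.41 ± 0.764 FPKM), and 0 higher (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00325, adjusted p = 0.446 with an estimated correlation). Directional fry did not call the immediate early, oligodendrocyte or ependymal lists (adjusted p = 0.0528, 0.478 and 0.156). Choroid plexus markers had 0 of 20 past the threshold (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.226, adjusted p = 0.865 with an estimated correlation). These markers were high in saline replicate 2 and LPS replicate 6, with list medians of 1.76 and 1.10 (log2 from the saline mean) against -1.18 to -0.77 in the other 4 libraries. The choroid plexus list was past the threshold, as lower, without saline replicate 1, saline replicate 3 or LPS replicate 6 (adjusted p = 0.00987, 0.0479 and 0.002, range over the camera alternatives 0.000164 to 0.946). It was also past it with sex as a covariate and without both libraries in which it is high (adjusted p = 0.000164 and 0.0203). Without those 2 libraries 794 genes were higher and 489 lower. Opalin, Gjb1 and Tmem107 lost their calls without saline replicate 1 (adjusted p = 0.0533 to 0.133). Gjb1 lost its call without saline replicate 2 (adjusted p = 0.0707). Gjb1 and Tmem107 lost their calls without saline replicate 3 (adjusted p = 0.0595 to 0.107). Gjb1 lost its call without LPS replicate 4 (adjusted p = 0.074). Gjb1 lost its call with sex as a covariate (adjusted p = 0.0847), with a range of 0.00308 to 0.157 over the alternatives for these genes.

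**Figure D4:**
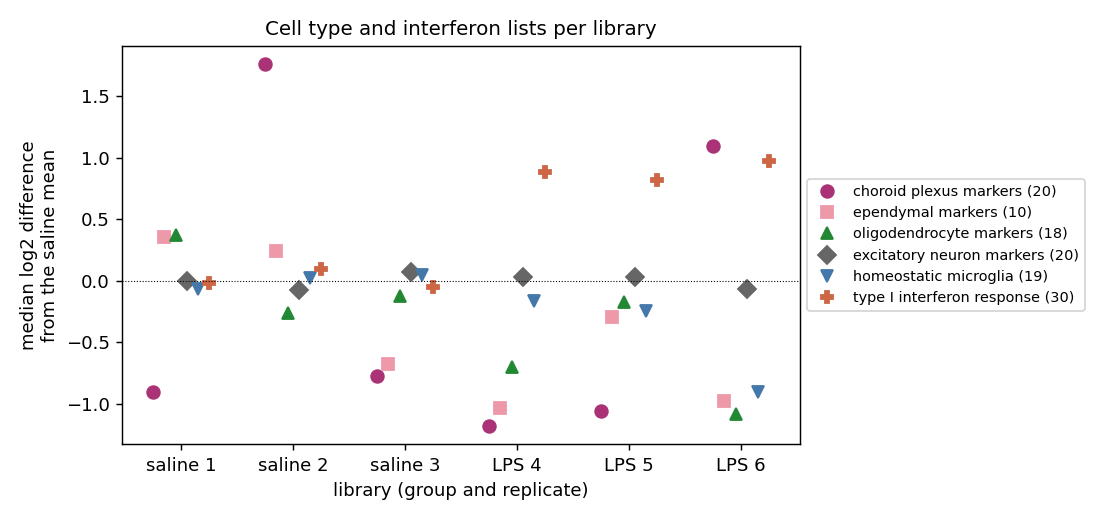
Median log2 difference from the saline mean (vertical axis, of log2(FPKM + 0.5)) over the tested members of 6 gene lists, in each of the 6 libraries (horizontal axis), with the number of members in parentheses. The choroid plexus markers are high in saline 2 and LPS 6, the type I interferon list lies between 0.82 and 0.98 in the LPS libraries, and the excitatory neuron markers lie between -0.07 and 0.07 in all 6.

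Other lists were not past the threshold. These were class II antigen presentation (1 higher and 1 lower of 4, H2-DMb1 and H2-DMa), pericytes and smooth muscle (0 and 1, Rgs5, of 12), and fibroblasts and meninges (1, Pdgfra, and 0 of 14). Also not past it were oligodendrocyte precursors (2, Pdgfra and Vcan, and 2, Olig2 and C1ql1, of 14), cell cycle (2, Cdkn1a and Pcna, and 1, Ccnd1, of 10) and oxidative stress (3, Cybb, Gclc and Srxn1, and 0 of 17). Likewise short of it were mitochondrially encoded genes (0 and 1, mt-Nd2, of 13) and erythrocytes (0 and 0 of 5). Without LPS replicate 6, however, 4 of 5 erythrocyte genes were lower, Hbb-bs, Hba-a1, Hbb-bt and Hba-a2 (adjusted p = 0.00351, 0.00824, 0.0156 and 0.0164, range over the alternatives for these genes 0.00351 to 1), and the list was past the threshold (adjusted p = 8.17e-05, range over the camera alternatives 6.07e-05 to 0.971). The median of the erythrocyte list stood -0.95, -0.71 and 0.75 from the saline mean (log2) in LPS replicates 4 to 6. The mitochondrial list was past the threshold, as lower, without saline replicate 1 (adjusted p = 0.0112, range over the camera alternatives 0.0112 to 0.857). The precursor list was so without saline replicate 2 or LPS replicate 5 (adjusted p = 0.0298 and 0.0309, range over the camera alternatives 0.0127 to 0.53). The region lists were not past it either, with thalamus at 1, Ramp3, and 1, Calb2, of 15, striatum at 1, Scn4b, and 0 of 11 and neocortex at 1, Lamp5, and 0 of 12. Dentate granule cells stood at 3, Pitpnm2, Pdzd2 and Maml2, and 0 of 15 and CA pyramidal cells at 1, Ociad2, and 1 of 14. The dentate list was past the threshold, as higher, without LPS replicate 6 (adjusted p = 0.0265, range over the camera alternatives 0.0265 to 0.831). Counts adjusted over the list alone were 1 higher and 2 lower for class II, 0 higher and 1 lower for pericyte, 1 higher and 0 lower for fibroblast, 2 higher and 4 lower for precursor. They were 2 higher and 1 lower for cell cycle, 5 higher and 1 lower for oxidative stress, 0 higher and 1 lower for mitochondrial, 0 higher and 0 lower for erythrocyte. For the region lists adjusted over the list alone they were 1 higher and 1 lower for thalamus, 1 higher and 1 lower for striatum, 0 higher and 0 lower for neocortex, 4 higher and 2 lower for dentate, 1 higher and 1 lower for CA. Camera adjusted p-values of these 13 lists ranged from 0.0734 to 1 and from 0.53 to 1 with an estimated correlation. In all, 25 of 46 lists were past the threshold with camera's preset correlation of 0.01, 16 up and 9 down, 25 with directional fry (22 of the same lists) and 0 with an estimated correlation (smallest adjusted p = 0.0694). The median, the mean and the camera direction of a list differed in sign for the PYHIN, class II, pericyte, excitatory neuron, cell cycle, neocortex and CA lists. H2-DMb1, H2-DMa, Pdgfra, Vcan, Olig2, C1ql1, Pcna, Ccnd1, Cybb, Gclc, Srxn1, mt-Nd2, Ramp3, Calb2, Scn4b, Lamp5, Pdzd2, Maml2 and Ociad2 lost their calls without saline replicate 1 (adjusted p = 0.0526 to 0.161). Vcan, Olig2, Pcna, Ccnd1, Gclc, Srxn1, mt-Nd2, Ramp3, Scn4b, Maml2 and Ociad2 lost their calls without saline replicate 2 (adjusted p = 0.076 to 0.133). H2-DMb1, Pdgfra, Olig2, C1ql1, Pcna, Ccnd1, Gclc, Srxn1, mt-Nd2, Ramp3, Scn4b, Lamp5, Pdzd2, Maml2 and Ociad2 lost their calls without saline replicate 3 (adjusted p = 0.0524 to 0.138). H2-DMb1, Olig2, C1ql1, Gclc, Srxn1, Ramp3 and Lamp5 lost their calls without LPS replicate 4 (adjusted p = 0.0548 to 0.105). Vcan, Olig2, Pcna, Srxn1, mt-Nd2, Scn4b, Pdzd2, Maml2 and Ociad2 lost their calls without LPS replicate 5 (adjusted p = 0.0529 to 0.102). C1ql1, Pcna, Srxn1, mt-Nd2, Ramp3, Lamp5 and Ociad2 lost their calls without LPS replicate 6 (adjusted p = 0.0504 to 0.102). H2-DMb1, Vcan, Olig2, C1ql1, Pcna, Ccnd1, Gclc, Srxn1, mt-Nd2, Ramp3, Scn4b, Lamp5, Pdzd2, Maml2 and Ociad2 lost their calls with sex as a covariate (adjusted p = 0.0514 to 0.106), with a range of 0.00255 to 1 over the alternatives for these genes.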

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

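Sex as a covariate, Ttr as a covariate and leaving out both libraries high in choroid plexus genes were chosen after seeing the data. Numb stayed short of the threshold under every alternative (adjusted p = 0.0796 to 1) and Ifi204 stayed past it under every alternative that tested it (adjusted p = 0.000197 to 0.00685). At a mean of at least 5 FPKM Ifi204 was not tested. Of the 2048 genes past the threshold, 0 changed sign under any alternative that tested them.

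Counts of genes moved by more than 1.5-fold under these alternatives. A mean of at least 5 FPKM, with fewer genes tested, gave 793 higher genes and 92 of the named genes (against 143). The fold minimum, a stricter test, gave 259 higher, 63 lower and 87 named genes. Sex as a covariate gave 574 higher and 274 lower, with 831 of the 2048 calls kept and 30 of the 143 named genes losing their call, beside 15 genes named after their values were seen, and leaving out both choroid-high libraries, which leaves 4, gave 794 and 489, with 1098 kept. More genes were lower with array weights (1247) and with Ttr as a covariate (1415), and the cause was not tested. With 1 library left out, higher genes ranged from 312 to 1077, lower genes from 92 to 762 and named genes from 88 to 134, and 12 to 55 named genes lost their call. Of the 143 named genes past the threshold, 81 stayed past it under every alternative that tested them.

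With an estimated correlation 0 of the 25 lists were past the threshold, so the calls made with camera rest on its preset. Fry, which takes no preset correlation, called 22 of the 25 and also the PYHIN, Notch and cGAS-STING lists. Of the 21 lists not past the threshold, 7 passed it with camera under at least 1 alternative, namely PYHIN, inhibitory neuron, erythrocyte, dentate, mitochondrial, choroid plexus and oligodendrocyte precursor. Elsewhere the lists of synaptic proteins, endothelial markers, cytokines, inflammasome genes and homeostatic microglia lost their calls under at least 1 alternative. The cytokine list turned at a mean of at least 5 FPKM (adjusted p = 0.825), where fewer of its members are tested. Reversed genes not past the threshold in the comparison, as log2 differences, were mt-Atp8 with quantile normalization (0.14), Jchain with both choroid-high libraries left out (-0.0545), and, over the 6 libraries left out in turn, Hba-a1 (-0.84 to 0.031), Hba-a2 (-0.81 to 0.0724), Prlr (-1.02 to 0.00948) and Calml4 (-1.47 to 0.15). For these genes the cause was not tested. No paired analysis was possible because the groups share no replicate numbers. Depth is unknown, so what it limits cannot be stated.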

Other observations

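The 6 gene families below, the genes named here that are not named in the report and all tests on the 3 patterns were chosen after the values were seen, and the splits of the libraries were planned. Camera p-values of the 6 families were adjusted over these 6 alone. The same values chose the families, so these p-values and the alternatives run for them are no independent test. Clustered histone genes, which encode proteins that pack DNA made in S phase, were lower after LPS. Of 17 tested, 11 fell and 0 rose (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 9.73e-09, adjusted p = 0.0666 with an estimated correlation), with H2bc4 going from 22.7 ± 1.03 to 11.5 ± 0.822 FPKM and H2ac19 from 12.1 ± 0.265 to 7.02 ± 0.773 FPKM (mean ± SD over 3 libraries). Nuclear-encoded subunits of the respiratory chain fell by little, 24 of 89 and 0 rose (0 higher and 31 lower adjusted over the list alone, camera adjusted p = 1.75e-10, adjusted p = 0.0666 with an estimated correlation), with a median log2 difference of -0.14, Atp5f1e going from 84 ± 3.22 to 61.6 ± 3.04 FPKM and Cox5a from 125 ± 2.85 to 101 ± 0.136 FPKM. Of 12 tubulin genes 5 fell and 1, Tubb6, rose (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 2.73e-05, adjusted p = 0.209 with an estimated correlation), with Tubb2b going from 106 ± 5.12 to 69.1 ± 8.28 FPKM, Tubb5 from 128 ± 8 to 92.2 ± 3.21 FPKM, and Tuba4a, Tubb3 and Tuba1a also lower. Without saline replicate 1 the calls went down to 4 histone, 3 respiratory chain and 2 tubulin genes. With no filter 16 of 61 histone genes fell, with a median log2 difference of -0.366 against -0.785 over the 17. The median of each of these 3 families lay below 0 under all 20 alternatives run for it. Tubb6, Tuba4a, Tubb3 and Tuba1a lost their calls without saline replicate 1 (adjusted p = 0.0526 to 0.0968). Tubb6, Tubb3 and Tuba1a lost their calls without saline replicate 2 (adjusted p = 0.0741 to 0.0957). Tubb6, Tuba4a and Tuba1a lost their calls without saline replicate 3 (adjusted p = 0.0609 to 0.105). Tubb6, Tubb3 and Tuba1a lost their calls without LPS replicate 5 (adjusted p = 0.0565 to 0.0676). Tubb6 lost its call without LPS replicate 6 (adjusted p = 0.0605). Tubb6 lost its call with sex as a covariate (adjusted p = 0.0732), with a range of 0.002 to 0.39 over the alternatives for these genes.

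Clock genes rose, 6 of 17 and 0 fell (8 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00185, adjusted p = 0.209 with an estimated correlation), with Per3 going from 8.34 ± 0.461 to 13.9 ± 0.773 FPKM. All 4 tested genes of the Ms4a family of membrane proteins rose (4 higher and 0 lower adjusted over the list alone, camera adjusted p = 9.64e-07, adjusted p = 0.0666 with an estimated correlation), Ms4a6b from 0.494 ± 0.175 to 4.85 ± 1.22 FPKM, beside Ms4a6c, Ms4a6d and Ms4a4a. The filter keeps members near 0 FPKM in saline only where they rise, and with no filter 4 of 12 tested members rose, with a median log2 difference of 0.148 against 2.78 over the 4. Among 74 cytosolic ribosomal protein genes 3, Rps18, Rpl7 and Rpl3, rose and 0 fell (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.918, adjusted p = 0.975 with an estimated correlation), and the direction of that list turned under 6 of 20 alternatives. Without saline replicate 1 the clock genes had 1 call. The cold-inducible RNA-binding protein genes Rbm3 and Cirbp rose from 51.4 ± 2.2 to 115 ± 10.9 FPKM and from 30.2 ± 3.11 to 67.3 ± 12.1 FPKM, Ly6a, a surface antigen gene, from 15 ± 0.701 to 92.2 ± 9.56 FPKM and the Wnt ligand gene Wnt10b from 0.372 ± 0.0112 to 4.64 ± 0.302 FPKM (adjusted p = 0.000384, 0.00334, 3.16e-05 and 9.13e-05, limma). Rps18, Rpl7 and Rpl3 lost their calls without saline replicate 1 (adjusted p = 0.1 to 0.124). Rps18, Rpl7 and Rpl3 lost their calls without saline replicate 2 (adjusted p = 0.0772 to 0.104). Rps18, Rpl7 and Rpl3 lost their calls without saline replicate 3 (adjusted p = 0.0974 to 0.106). Rpl3 lost its call without LPS replicate 4 (adjusted p = 0.074). Rps18, Rpl7 and Rpl3 lost their calls without LPS replicate 5 (adjusted p = 0.0518 to 0.082). Rpl7 and Rpl3 lost their calls without LPS replicate 6 (adjusted p = 0.0624 to 0.0725). Rpl7 and Rpl3 lost their calls with sex as a covariate (adjusted p = 0.0887 to 0.0936), with a range of 0.00488 to 1 over the alternatives for these genes.

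The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 5%. The real split gave 1221 higher and 827 lower genes and the highest other split 4 in 1 direction, so 1 split of 10 gave as many higher genes and 1 as many lower genes. For gene lists past the threshold the real split gave 25 and the highest other 26, so 2 splits gave as many. Every other split called lists, namely 15, 23, 22, 20, 26, 17, 15, 19 and 9, although few or no genes passed in it. The count of lists past camera's threshold therefore does not separate the real split from mixed groupings of saline and LPS libraries.

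Choroid plexus genes were high in saline replicate 2 and LPS replicate 6, with Ttr at 17.5, 1906, 88.6 FPKM in saline and 6.33, 15.1, 1558 FPKM in LPS. LPS as the whole cause is argued against by the pattern itself, since saline replicate 2 was given no LPS. The median difference of the markers from the others of the group was 2.64 (log2) for saline replicate 2 and 2.25 for LPS replicate 6. These 2 libraries were picked as high in the markers, so the medians give the size of the pattern and do not test it. Sex is not a full account, since LPS replicate 5, also female, lay -0.06 from the males. Of 20 tested markers 19 were higher in both libraries than in each of the other 4, which restates the pattern, so choroid plexus tissue carried into these 2 dissections stays open as a candidate source. No biological explanation beyond LPS and sex was tested.

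Oligodendrocyte genes were lower in LPS replicate 6 than in LPS replicates 4 and 5, with Mog at 32.9, 19.6, 24.3 FPKM in saline and 12.6, 17.7, 2.72 FPKM in LPS. Fewer oligodendrocytes as the whole cause would lower all markers alike, if transcript levels per cell were alike in the LPS mice. The deviations over the 18 markers had an SD of 0.65 (log2), 3.59 times the largest between other libraries of 1 group (0.181). They ran from -2.26 for Mog to -0.051 for Apod. This argues against an equal loss alone. LPS moved markers of this list both ways, so a loss of cells beside a change in transcript levels per cell is not excluded. Dilution by choroid plexus tissue is argued against by excitatory neuron markers, whose median deviation of -0.12 (log2, SD 0.30) lay 0.59 above that of the oligodendrocyte markers. A stronger response to LPS in that mouse stays open, since 64.5% of 1829 genes past the threshold without it and outside the oligodendrocyte and choroid plexus lists (1180) lay further from saline in it than in the mean of the other 2. Not all LPS-responsive lists did, since medians from the saline mean (log2) in LPS replicates 4 to 6 were 1.278, 1.309 and 1.203 for glucocorticoid-responsive genes, 1.143, 0.886 and 0.943 for activated microglia and 3.213, 2.977 and 2.293 for neutrophil markers. Differences in the dissected region or in the age of the mice were not tested.

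Microglial genes moved apart after LPS, with 26 of 52 tested higher and 9 lower over the 2 microglial lists and the 3 C1q genes. Among the 42 of them with a saline mean of at least 1 FPKM, 42.9% (18 genes) rose. A loss of microglia alone does not account for this rise, since a loss of cells raises none. The rise is part of the pattern as it was chosen, so its share restates the pattern and does not test it. Whether a loss of microglia adds to the fall stays open. Dilution by blood monocytes and neutrophils as the cause of the fall is argued against by the 20 excitatory neuron markers, since added cells lower transcripts of all brain cells alike. Their median log2 difference was 0.023 (SD 0.26), against -1.41 for the 9 genes that fell. For the rise, blood monocytes and neutrophils stay open. With no filter 12 of 30 markers of neutrophils, monocytes and border macrophages were higher and 0 lower, many of them near 0 FPKM. Monocyte and border macrophage markers form 1 list, so this count does not tell blood cells from border macrophages. Among the 12 were Ngp, Retnlg and Chil3 (adjusted p = 0.0019, 0.017 and 0.00305, limma with no filter), at or near 0 FPKM in saline. However, Lcn2 and Vcan are also made by other brain cells, and Ly6g was listed at 0 FPKM in each library. Csf3r, Ccr2, Camp, Mpo, Ltf and Cxcr2 were not past the threshold (adjusted p = 0.35, 0.74, 0.501, 0.483, 0.903 and 0.136, limma with no filter). A change of state within microglia is a further candidate explanation, and was not tested.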
